A study of Mus musculus with 6 samples.

How the data were processed

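Bulk RNA-seq was made from mouse lung cells that the labels name Schwann cells, the glial cells of peripheral nerves. Per the labels' protocols, cells were sorted from female hGFAP-tdTomato mice aged 12 to 16 weeks as CD45-negative, EPCAM-negative, CD31-negative and tdTomato-high. They were cultured for 8 days in DMEM with 10% foetal bovine serum and then given PBS or LPS at 20 ng/mL for 2 h. Per the labels' protocols, cDNA was made from 2 ng of total RNA with the Smart-Seq v4 kit, and 150 pg of cDNA went into Nextera XT libraries. These kits do not mark the strand, so reads of a gene and of an antisense partner cannot be told apart where they overlap. The labels give 3 PBS and 3 LPS libraries. They do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

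Per the submitters' processing notes, reads were aligned with GSNAP to GRCm38. The versions, the counting program, the annotation release and the treatment of reads with several matches are not given in the sources used here. The authors deposited whole-number read counts per Ensembl gene, with no normalization, for 52636 genes per library. Per the file headers, an RPKM value stands beside each count. The deposited RPKM values equal the count divided by the width column and a library total of 37789622 to 58225894, and the summed counts made up 86.2% to 89.2% of that total. The width equalled the genomic span of the gene, introns included, for 85.6% of matched genes. RPKM was used only for this check.

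Gene symbols, positions and types came from the GENCODE annotation of GRCm38, matched by Ensembl identifier. This left 233 genes unmatched, which held 0.0230% to 0.0460% of counts per library. For every gene the exonic share overlapped by other annotated genes was computed with bedtools 2.31.1. Coding genes with all exons inside other genes were at 0 in every library in 81.8% of 1437 cases, against 23.0% of 14024 coding genes without overlap. A 0 of such a gene therefore cannot be taken as a lack of expression.

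Total counts were 51933344, 51191823 and 40427700 in PBS libraries 1 to 3 and 34423461, 32650693 and 34719608 in LPS libraries 1 to 3. Scaled to the total, a count of 0 allows up to 3 counts, or 0.0578 to 0.0919 CPM, and covers counting error only because no molecular identifiers were used. Fold changes against a group at 0 in all its libraries are lower bounds against 3 counts per library. For genes with 1 to 3 counts over the PBS libraries, the ratio of summed rates is given with an exact 95% binomial interval.

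Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test, TMM factors and the default expression filter, which kept 15512 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values (counts scaled to a common total of 1e6) use TMM-scaled library sizes, and values are means with the SD of 3 libraries. The 28 gene lists were tested with camera at a preset correlation of 0.01 for lists with at least 5 tested members, with adjustment over the 27 lists tested. Library composition was compared with exact two-sided permutation tests, which cannot give a p under 0.1 with 3 against 3.

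Lists, tests and the rule for named genes were fixed before the data were examined. The rule took the 12 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM, a symbol that is not a predicted-gene name and no overlap between the groups. It added from each list up to 4 called members with the largest change, or the 2 most abundant members where fewer than 2 were called. It always took a fixed set that included Tlr4, Cd14, Ly96, S100b, Sox10, Gfap, Ngfr, Ptprc, Epcam and Pecam1, and some genes under the rule are not reported here. Members named only for a count adjusted over the list alone were chosen after their values were seen.

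The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no low-count filter, a minimum count of 50, a replicate block, each library left out in turn, an adjusted p under 0.01 and a 1.5-fold threshold. DESeq2 was also run without the low-count filter, so its counts differ in both method and filter. For the lists they were an estimated correlation and fry. After the data were seen, 3 were added: leaving out PBS libraries 1 and 2 together (which leaves 1 PBS library, so that the spread comes from the LPS libraries alone), offsets for exon length and GC content from a loess with a span of 0.3, and limma-voom with library weights. Replicate pairs were compared by chi-square over genes, and every pair differed by more than counting error alone (21.2 to 832 per degree of freedom). This does not tell technical from biological differences. The tests were tried on simulated counts of 15512 genes with 200 changed. In the simulated counts 8.96% of 2-fold, 79.1% of 4-fold and 100% of 16-fold changes were called, and 5.30% of 132 calls were false. Counts were drawn independently around a common mean per gene, and only genes with a mean of at least 5 CPM were changed. The simulation held no difference shared across genes like that between PBS libraries 1 and 2 and PBS library 3. These shares therefore need not hold for the real libraries.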

Results

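The series measured the transcriptome of cells that the labels name cultured lung Schwann cells. They were given lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria, or PBS as the control for 2 h. Schwann cell markers were low (list median 0.660 CPM, against 13.9 CPM for fibroblast markers). Which cells in the culture gave the response is therefore not settled. Schwann cells ensheath peripheral axons, and the series title names non-myelinating Schwann cells and a pro-inflammatory response in the lung. There were 3 libraries per group. Summed counts were 51933344, 51191823 and 40427700 in PBS libraries 1 to 3 and 34423461, 32650693 and 34719608 in LPS libraries 1 to 3, and 20571 to 21229 genes had at least 1 count.

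The control libraries were not alike. The first principal component of log2 CPM held 74.3% of the variance and separated PBS libraries 1 and 2 from PBS library 3 and the LPS libraries. Across genes, which are not independent replicates, the Spearman correlation of PBS library 3 was 0.926 and 0.943 with PBS libraries 1 and 2, and 0.986, 0.974 and 0.973 with LPS libraries 1 to 3. The most abundant gene was Thbs1, which encodes the matrix protein thrombospondin 1, in PBS libraries 1 and 2, and Spp1, which encodes osteopontin, in the other 4. PBS library 3 nevertheless held 54 reads of the chemokine gene Cxcl1, close to the 70 and 28 reads of PBS libraries 1 and 2 and far from the 71450 to 93499 reads of the LPS libraries. Cxcl2, Saa3, Ccl7 and Il6 were higher in PBS library 3 (0.793, 2.21, 61.2 and 159 CPM) than in PBS library 1 (0.149, 0.504, 16.1 and 45.7 CPM) and PBS library 2 (0.0189, 0.436, 18.2 and 66.6 CPM), and below all LPS libraries. Other genes that rose after LPS went the other way and were lowest in PBS library 3. Among them were Tnfaip3 (41.7, 31.5 and 11.3 CPM in PBS libraries 1 to 3), Lif (20.1, 15.6 and 7.07 CPM) and Nfkbiz (32.0, 22.8 and 17.5 CPM). Mitochondrial genes took 0.0997%, 0.135% and 0.498% of counts in the PBS libraries and 0.423%, 0.838% and 0.993% in the LPS libraries (exact permutation test, p = 0.2, adjusted p = 0.3 over 6 measures). Ribosomal protein genes took 0.334% ± 0.230 in PBS and 0.777% ± 0.161 in LPS (SD, n = 3, exact permutation test, p = 0.2, adjusted p = 0.3). The 100 most abundant genes took 19.3% ± 1.57 in PBS and 23.5% ± 1.39 in LPS (SD, n = 3, exact permutation test, p = 0.1, adjusted p = 0.3). The total count of every LPS library was below that of every PBS library (exact permutation test, p = 0.1, adjusted p = 0.3). The number of genes detected (exact permutation test, p = 0.3, adjusted p = 0.36) and the haemoglobin share (exact permutation test, p = 1, adjusted p = 1) did not pass either. No measure could pass, because such a test cannot give a p under 0.1 with 3 libraries against 3.

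**Figure D1:**
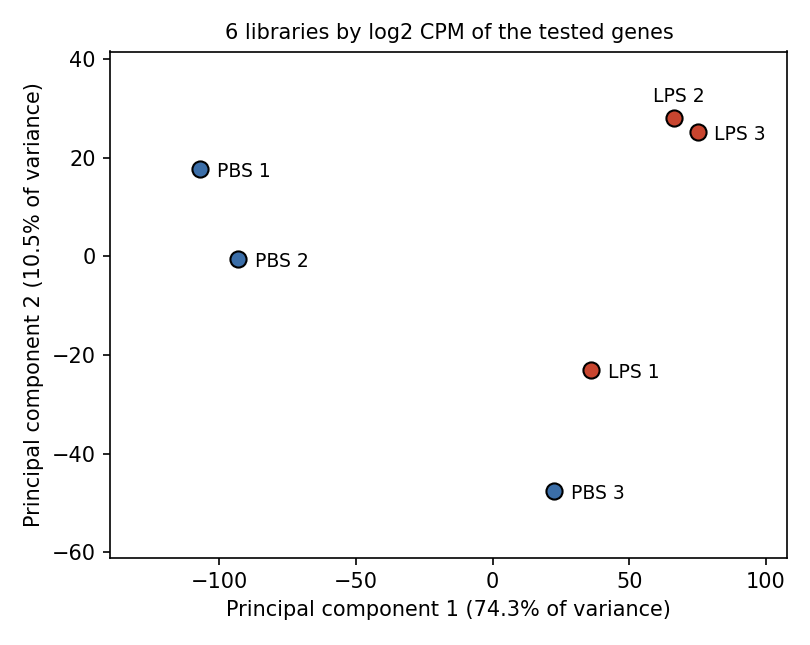
Each point is 1 library, placed by its first (74.3% of the variance) and second (10.5%) principal components of log2 CPM over the tested genes, in arbitrary units, with PBS in blue and LPS in red. PBS libraries 1 and 2 lie at -107 and -93.0 on the first component, whereas PBS library 3 lies at 22.5 beside LPS library 1 at 36.0.

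LPS against PBS asks which genes respond to the bacterial product within 2 h. Genes for neutrophil-attracting chemokines, colony-stimulating factors and NF-kB feedback inhibitors were among those that rose after LPS. Cxcl1, whose product attracts neutrophils, went from 1.05 ± 0.446 CPM in PBS to 2403 ± 355 CPM in LPS (SD, n = 3, log2 fold change 11.17, SE 0.61, edgeR adjusted p = 9.7e-05). Ccl20, which attracts cells bearing the receptor CCR6, went from 4.88 ± 3.07 to 4261 ± 1106 CPM (SD, n = 3, log2 fold change 9.77, SE 0.72, edgeR adjusted p = 0.00035). Csf2, which encodes the growth factor GM-CSF, had 0 reads in all 3 PBS libraries and 52.2 ± 13.9 CPM in LPS (SD, n = 3), at least 846-fold higher (edgeR adjusted p = 0.00022).

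Of 15512 genes tested by edgeR's quasi-likelihood test, 84 were higher and 4 lower after LPS. All 84 were at least 2-fold higher, and all 88 had no overlap between the groups. The genes were called on these same values, so the lack of overlap adds no separate support. Before adjustment, 2305 genes were higher and 3206 lower at a p under 0.05. The counts of 84 and 4 changed with the method and with the libraries used. DESeq2, run on 25559 genes without the low-count filter, gave 1516 higher and 2154 lower genes. Without that filter edgeR gave 1075 and 1962, and with the replicate block 2144 and 2109 of the 15512 genes. RLE factors gave 91 and 3, and unweighted limma-voom 94 and 3. Without PBS libraries 1 and 2, a setting chosen after seeing the data, PBS library 3 is the only control and the spread comes from the LPS libraries alone. In that fit 50 genes were higher, 42 of them among the 84, and 1 was lower, which was none of the 4. Without PBS library 3, 4303 of 15942 tested genes were higher and 4885 lower, including all 84 and all 4. Leaving out any other single library gave 24 to 50 higher and 0 lower genes, and all 84 kept a positive fold change in each of these fits. With no overlap between the groups, leaving out libraries could hardly change that sign. The kept sign therefore adds no separate support. Fold changes also followed exon length, with a median log2 fold change of 0.66, -0.12, -0.38 and -0.28 over 4 groups of 3872 genes each, from the shortest to the longest. With offsets for exon length and GC content, 128 were higher and 27 lower, and the log2 fold change of Ccl20 went from 9.77 to 8.98 and that of Ccl7 from 6.26 to 5.50.

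The 12 largest increases named by the rule were Csf2, Cxcl2, Cxcl1, Ccl20, Csf3, Saa3, Ccl7, Cxcl3, Irf1, Slfn2, Ccrl2 and Ch25h. Slfn2, of a family linked to growth control of immune cells, went from 0.779 ± 0.420 to 20.4 ± 4.57 CPM (SD, n = 3), although other annotated genes overlap 86.1% of its exonic bases. Its log2 fold change of 4.72 went to 4.04 without PBS libraries 1 and 2. Ccrl2, an atypical receptor that binds chemerin, went from 0.418 ± 0.370 to 10.7 ± 2.64 CPM (SD, n = 3, log2 fold change 4.66, edgeR adjusted p = 0.013), with a log2 fold change of 5.64 without PBS library 1. Without LPS library 1 its adjusted p was 0.13, the highest over all settings, which started at 1.2e-21. Among the lower genes were Zfp316, a zinc finger gene (log2 fold change -3.33, edgeR adjusted p = 0.045), Prss35, a serine protease gene (-2.41, adjusted p = 0.045), and Arrdc3, which encodes an arrestin-domain protein (-1.82, adjusted p = 0.040). The last lower gene, 9930012K11Rik (-2.57, edgeR adjusted p = 0.034), was chosen after its values were seen. Zfp316 had 1147, 656 and 150 reads in PBS libraries 1 to 3 and 46, 29 and 48 in LPS libraries 1 to 3. None of Zfp316, Prss35 and Arrdc3 was called against PBS library 3 as the only control (log2 fold change -1.55, -1.55 and -1.35, adjusted p = 0.66, 0.31 and 0.23), nor without any single library other than PBS library 3 (highest adjusted p = 0.23, 0.24 and 0.27). Over all settings their adjusted p began at 1.7e-09, 1.3e-08 and 3.3e-09.

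**Figure D2:**
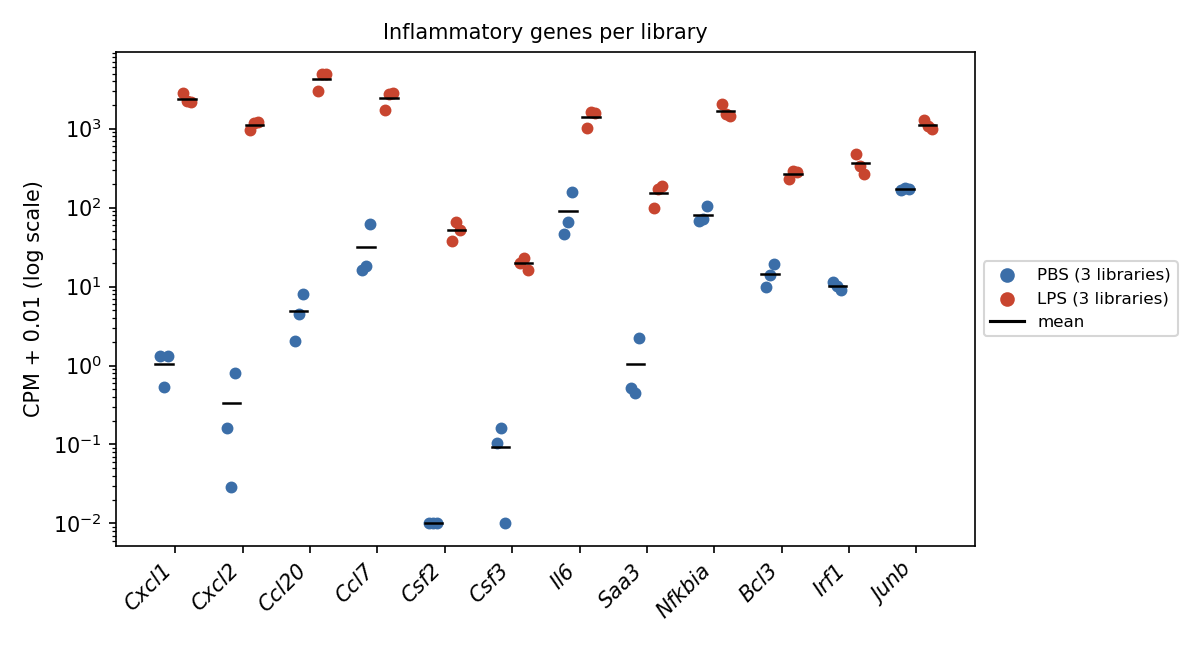
Points are single libraries (PBS blue, LPS red, n = 3 each) and black lines are group means of CPM + 0.01 on a log axis, for 12 genes of the chemokine, cytokine, acute phase, NF-kB, interferon and immediate early lists. For each gene drawn, all 3 LPS libraries lie above all 3 PBS libraries, and Csf2 has 0 reads in the PBS libraries.

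Of the 23 chemokines, 13 were tested, and 8 rose, none fell and 5 did not pass. Adjusted over the list alone, 9 were higher, Ccl5 being the addition. Cxcl2 went from 0.321 ± 0.415 to 1120 ± 142 CPM (SD, n = 3, log2 fold change 11.82, SE 1.08, edgeR adjusted p = 0.0012). Its log2 fold change was 13.62 without PBS library 3 and 10.44 without PBS libraries 1 and 2, and that of Ccl7 was 7.13 and 5.30. Ccl7, which attracts monocytes, went from 31.8 ± 25.4 to 2431 ± 600 CPM (SD, n = 3, log2 fold change 6.26, SE 0.66, edgeR adjusted p = 0.0027). Cxcl3, another ligand of the neutrophil receptor CXCR2, rose by 6.24 on the log2 scale (edgeR adjusted p = 0.00018). Cxcl1 (90891241 to 90893115), Cxcl2 (90903871 to 90905938) and Cxcl3 (90786103 to 90789600) lie together on chromosome 5 of GRCm38. They are related in sequence, and counting of reads that match several genes is not given, so their individual values are uncertain. Counts refer to whole genes and do not separate exons from introns. The list as a whole shifted upward (camera adjusted p = 2.1e-28), also with an estimated correlation (adjusted p = 0.013, but 0.065 against PBS library 3 alone). Ccl2 and Cxcl10 were listed at 0 in every library. Other annotated genes overlap 100% of their exonic bases, so these values cannot be taken as a lack of expression.

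Of the 25 cytokines, 16 were tested, and 5 rose, none fell and 11 did not pass. Adjusted over the list alone, 8 were higher. Csf3, which encodes the neutrophil growth factor G-CSF, went from 0.0816 ± 0.0765 to 19.7 ± 3.42 CPM (SD, n = 3, log2 fold change 7.79, SE 0.65, edgeR adjusted p = 0.00066). Its log2 fold change ranged from 7.27 to 8.49 with 1 library left out, and PBS library 3 held 0 of its reads. Il6 went from 90.6 ± 60.6 to 1404 ± 332 CPM (SD, n = 3, log2 fold change 3.95, SE 0.53, edgeR adjusted p = 0.011), with a log2 fold change of 4.62 without PBS library 3 and 3.12 without PBS libraries 1 and 2. Il23a, a subunit of interleukin 23, went from 0.0914 ± 0.0537 to 4.80 ± 2.26 CPM (SD, n = 3, log2 fold change 5.64, edgeR adjusted p = 0.0034). Csf2 lies on chromosome 11 (54247271 to 54249667), and other annotation overlaps 58.9% of its exonic bases. Il6 lost its call without LPS library 1, LPS library 3 or PBS library 2 (adjusted p = 0.093, 0.060 and 0.055; 3.6e-15 to 0.093 over all settings). Il23a lost it without LPS library 1 and without PBS libraries 1 and 2 (adjusted p = 0.057 and 0.075, from 2.8e-19 over all settings), where its log2 fold change was 5.33 and 6.53. The list shifted upward (camera adjusted p = 4.0e-15), also with an estimated correlation (adjusted p = 0.013, but 0.13 against PBS library 3 alone).

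All 25 genes of the NF-kB pathway and its feedback were tested, and 10 rose, none fell and 15 did not pass. Adjusted over the list alone, 16 were higher. Nfkbia, which encodes the inhibitor IkB-alpha, went from 81.2 ± 21.2 to 1675 ± 313 CPM (SD, n = 3, log2 fold change 4.37, SE 0.39, edgeR adjusted p = 0.0011). Bcl3, an atypical IkB protein, rose by 4.20 on the log2 scale (edgeR adjusted p = 0.00099). Zc3h12a, which encodes the RNase regnase-1, rose by 3.82 (edgeR adjusted p = 0.00059), and Nfkbiz by 3.40 (edgeR adjusted p = 0.0018). As a list these genes shifted upward (camera adjusted p = 5.6e-18; adjusted p = 0.079 with an estimated correlation).

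Of the 34 interferon-stimulated genes, 29 were tested, and 3 rose, none fell and 26 did not pass. Adjusted over the list alone, 5 were higher, with Gbp7 and Iigp1 added. Irf1, a transcription factor of interferon responses, went from 10.2 ± 1.19 to 363 ± 108 CPM (SD, n = 3, log2 fold change 5.16, SE 0.38, edgeR adjusted p = 0.00035). The guanylate-binding protein genes Gbp5 and Gbp2 rose by 4.83 and 2.08 on the log2 scale (edgeR adjusted p = 0.011 and 0.034). Gbp5 was not called without LPS library 1 or without PBS libraries 1 and 2 (adjusted p = 0.12 and 0.23, from 7.7e-13 over all settings), where its log2 fold change was 4.91 and 4.97. Gbp2 was not called without PBS library 1 or any single LPS library (adjusted p up to 0.18, from 1.1e-07 over all settings), and its log2 fold change was 2.68 without PBS libraries 1 and 2. The interferon-stimulated list shifted upward (camera adjusted p = 0.00066; adjusted p = 0.13 with an estimated correlation), but not without PBS library 3 (adjusted p = 0.065).

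Of 25 immediate early genes, 24 were tested, and 4 rose, none fell and 20 did not pass; 10 were higher and 1, Fos, lower when adjusted over the list alone. Junb, a subunit of the transcription factor AP-1, went from 173 ± 5.69 to 1122 ± 161 CPM (SD, n = 3, log2 fold change 2.70, SE 0.32, edgeR adjusted p = 0.0053). Fosl1, another AP-1 subunit with 57.2% of its exonic bases overlapped, rose by 2.52 on the log2 scale (edgeR adjusted p = 0.0040). Ier3 and Egr1 rose by 2.21 and 1.82 (edgeR adjusted p = 0.034 and 0.025). Junb was not called without PBS library 2 (adjusted p = 0.055; from 2.1e-18 over all settings). Ier3 and Egr1 were called without PBS library 3 but not without any other single library (highest adjusted p = 0.20 and 0.17), and Ier3 not without PBS libraries 1 and 2 (log2 fold change 2.20, adjusted p = 0.31; over all settings from 7.7e-09 for Ier3 and 1.3e-08 for Egr1). The list shifted upward (camera adjusted p = 1.9e-05; adjusted p = 0.35 with an estimated correlation).

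All 22 MAP kinase phosphatases and mRNA decay factors were tested, and 3 rose, none fell and 19 did not pass. Adjusted over the list alone, 6 were higher and 5 lower, the lower ones being Dusp1, Dusp4, Dusp6, Dusp10 and Spry1. Zfp36l1 and Zfp36, whose products bind AU-rich mRNA and promote its decay, rose by 3.42 and 1.65 on the log2 scale (edgeR adjusted p = 0.017 and 0.035), although 90.2% and 36.7% of their exonic bases are overlapped. Cish, a feedback inhibitor of cytokine receptors, rose by 2.13 (edgeR adjusted p = 0.015). None of Zfp36l1, Zfp36 and Cish was called against PBS library 3 as the only control (log2 fold change 2.55, 1.82 and 2.18, adjusted p = 0.073, 0.095 and 0.095). Each also lost its call without 4 or 5 of the 6 single libraries (highest adjusted p = 0.12, 0.22 and 0.13; from 7.4e-15, 4.2e-08 and 3.0e-08 over all settings). The list did not shift (camera adjusted p = 0.70), except upward against PBS library 3 as the only control (adjusted p = 0.0063, but 0.25 with an estimated correlation), and its median log2 fold change of -0.18 and its mean of 0.04 differ in sign.

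Of the 15 adhesion genes, 14 were tested; 1, Sele, rose, none fell and 13 did not pass. Sele, which encodes the leukocyte-binding E-selectin, had 0, 3 and 0 reads in PBS and 100, 66 and 81 in LPS, a ratio of 123 (exact 95% interval 41.8 to 603, counting error only; edgeR adjusted p = 0.0052, 0.093 without LPS library 1 and from 2.9e-16 over all settings). Adjusted over the list alone, 4 were higher, with Madcam1, Vcam1 and Icam1 added. Vcam1 had 107 ± 37.0 CPM in PBS and 337 ± 20.0 CPM in LPS (SD, n = 3, log2 fold change 1.65, edgeR adjusted p = 0.079), but was called against PBS library 3 as the only control (2.37, adjusted p = 0.022). Itgav had 194 ± 65.4 and 201 ± 39.1 CPM (SD, n = 3, edgeR adjusted p = 0.93). The adhesion list shifted upward (camera adjusted p = 0.0020; adjusted p = 0.18 with an estimated correlation), but not without PBS library 3 (adjusted p = 0.13).

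Of 19 prostanoid, nitric oxide and oxidative enzymes, 18 were tested, and 5 rose, none fell and 13 did not pass; 7 were higher and 4 lower, Hmox1, Ptgs1, Gclc and Srxn1, when adjusted over the list alone. Ch25h, which makes 25-hydroxycholesterol, went from 6.13 ± 1.54 to 142 ± 21.5 CPM (SD, n = 3, log2 fold change 4.53, SE 0.35, edgeR adjusted p = 0.00038). Nos2, the inducible nitric oxide synthase gene, had 0, 1 and 0 reads in PBS and 73, 76 and 77 in LPS, a ratio of 339 (exact 95% interval 60.2 to 13446, counting error only; edgeR adjusted p = 0.0012). Acod1, which makes itaconate, had 0 reads in the PBS libraries and 45, 14 and 15 in LPS, at least 12.1-fold higher (edgeR adjusted p = 0.041). Steap4, a metalloreductase gene, rose by 3.61 on the log2 scale (edgeR adjusted p = 0.014), by 3.16 without PBS library 3 and by 5.31 without PBS libraries 1 and 2. The last was Slc7a11, which encodes the cystine transporter and was chosen after its values were seen. Acod1 was not called without PBS libraries 1 and 2 (14 to 45 reads against 0 in PBS library 3, adjusted p = 0.51) or without any single library other than PBS library 3 (highest adjusted p = 0.15; from 2.8e-08 over all settings), nor Steap4 without LPS library 1 or 3 (highest adjusted p = 0.13; from 3.4e-16). The list shifted upward (camera adjusted p = 0.00098; adjusted p = 0.30 with an estimated correlation), but not without PBS library 3 (adjusted p = 0.21).

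Of 16 acute phase and complement genes, 11 were tested, and 3 rose, none fell and 8 did not pass; 3 were higher and 1, C4b, lower when adjusted over the list alone. Saa3, an acute phase protein gene, went from 1.05 ± 1.01 to 153 ± 48.6 CPM (SD, n = 3, log2 fold change 7.20, SE 0.73, edgeR adjusted p = 0.0020), with a log2 fold change of 8.31 without PBS library 3 and 6.09 without PBS libraries 1 and 2. Lcn2, which binds bacterial siderophores, went from 5.57 ± 3.80 to 58.3 ± 3.48 CPM (SD, n = 3, log2 fold change 3.39, edgeR adjusted p = 0.013), with a log2 fold change of 4.08 without PBS library 3 and 2.54 without PBS libraries 1 and 2. Serpina3g, of a family of near copies that reads may not separate, rose by 3.77 on the log2 scale (edgeR adjusted p = 0.0040) and by 4.54 without PBS libraries 1 and 2. Without LPS library 1 neither Lcn2 nor Serpina3g was called (adjusted p = 0.12 and 0.058; from 8.0e-15 and 2.9e-13 over all settings), and Lcn2 not without LPS library 3. The list shifted upward (camera adjusted p = 0.019; adjusted p = 0.20 with an estimated correlation), but not without PBS library 3 (adjusted p = 0.12) or without LPS library 1. All 19 genes of the integrated stress response were tested, and Gadd45b alone rose, by 2.63 on the log2 scale (edgeR adjusted p = 0.011; up to 0.096 without 1 of 4 single libraries, PBS library 2 and each LPS library, and from 1.5e-12 over all settings), as it did alone when adjusted over the list alone. Hspa5 and Xbp1, genes of the unfolded protein response, did not pass (edgeR adjusted p = 0.10 and 0.69), nor did the list (camera adjusted p = 0.70).

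**Figure D3:**
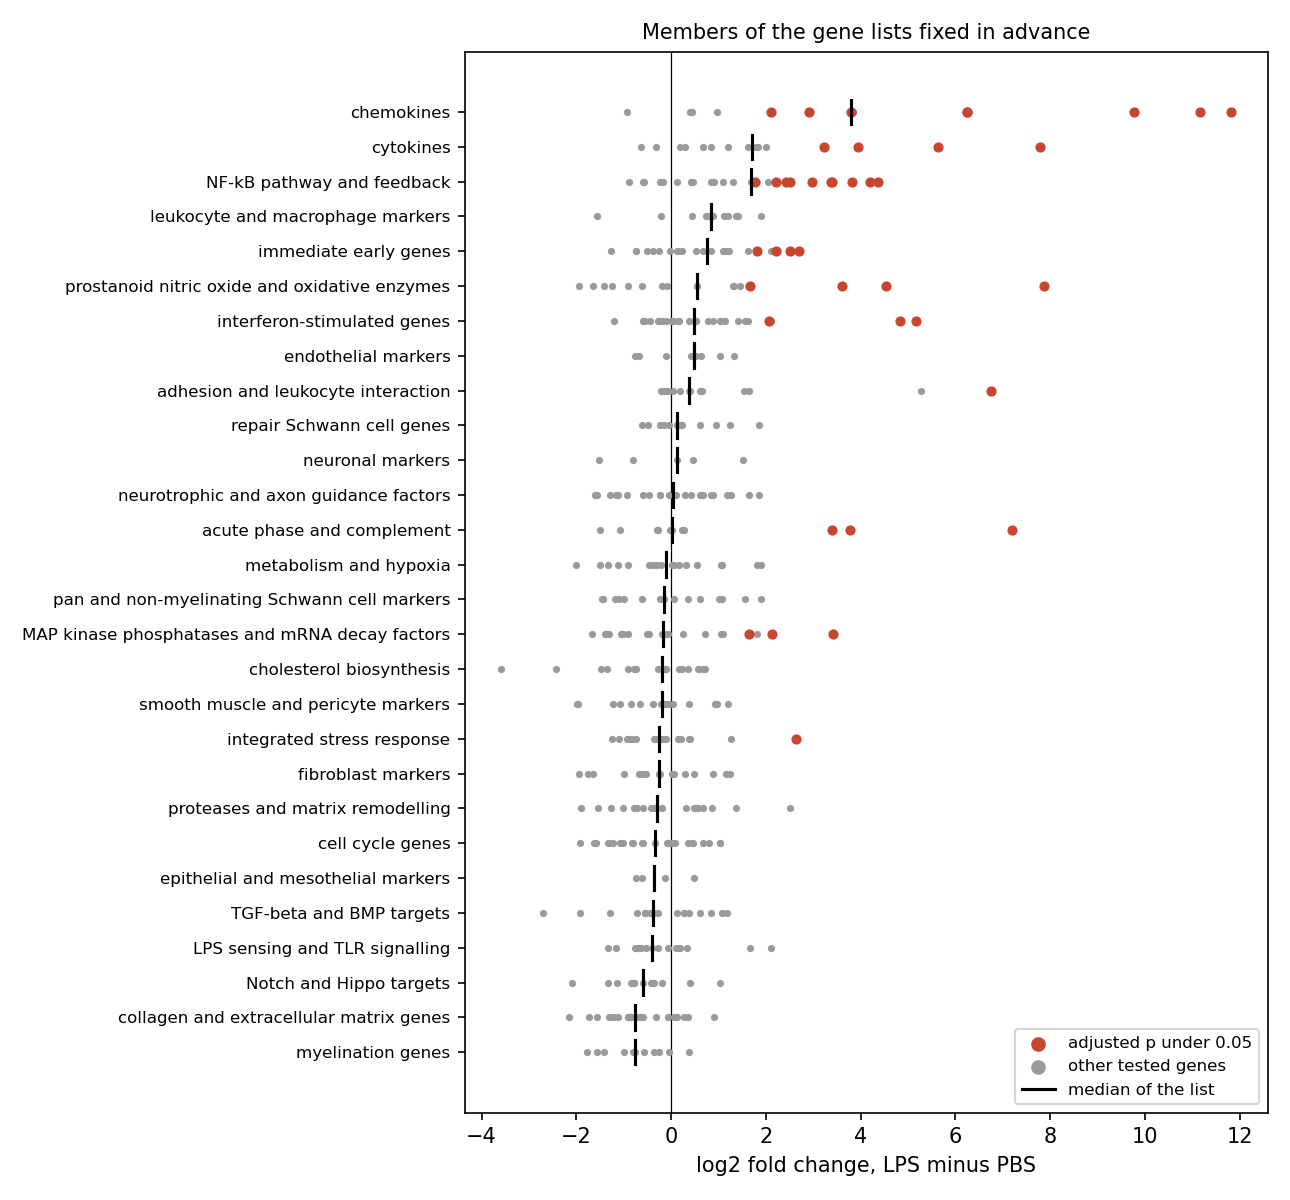
Each point is 1 tested gene at its edgeR log2 fold change (LPS minus PBS), in rows by gene list, red where the adjusted p was under 0.05, and black bars are list medians. Genes with 0 reads in all PBS libraries, such as Csf2 and Acod1, are left out of the points but not of the medians, the highest of which is 3.79 for the chemokines.

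The LPS receptor genes were expressed in both groups. Tlr4 had 123 ± 2.87 CPM in PBS and 102 ± 7.62 in LPS (SD, n = 3, edgeR adjusted p = 0.46), and Cd14 had 62.5 ± 23.6 and 78.8 ± 12.6 (SD, n = 3, edgeR adjusted p = 0.47). Ly96, which encodes the TLR4 partner MD-2, had 27.5 ± 22.4 and 87.4 ± 30.2 CPM (SD, n = 3, edgeR adjusted p = 0.093), with 2218 reads in PBS library 3 against 743 and 803 in PBS libraries 1 and 2. Irak1, a kinase downstream of TLR4, had 130 ± 66.2 and 51.9 ± 2.63 CPM (SD, n = 3, edgeR adjusted p = 0.093). None of the 17 tested members of 20 in LPS sensing and TLR signalling was called, although 3 were higher and 7 lower without PBS library 3, and Tlr2 alone passed, higher, when adjusted over the list alone (camera adjusted p = 0.70). Without PBS library 3, 4303 of all 15942 tested genes were higher and 4885 lower.

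The list of pan and non-myelinating Schwann cell markers had a median of 0.337 to 0.909 CPM per library, 11 of its 25 members had a mean of at least 1 CPM, and none was called with all libraries. Without PBS library 3, 3 of these markers were higher and 6 lower, as were 0 and 6 of the myelination genes and 2 and 1 of the repair Schwann cell genes. Of all 15942 genes tested in that fit, 4303 were higher and 4885 lower. S100b, a glial calcium-binding protein gene with 83.0% of its exonic bases overlapped, had 1.93 ± 0.485 CPM in PBS and 3.86 ± 0.751 in LPS (SD, n = 3, edgeR adjusted p = 0.10). Sox10, the transcription factor of the Schwann lineage, had 0.521 ± 0.343 and 0.798 ± 0.715 CPM (SD, n = 3, edgeR adjusted p = 0.60). Ngfr had 42, 34 and 0 reads in PBS and 6, 3 and 12 in LPS (edgeR adjusted p = 0.42). Gfap was listed at 0, with 100% of its exonic bases overlapped. This value says nothing about the activity of the hGFAP-tdTomato reporter. The most abundant members were Cdh2, with 202 ± 105 and 75.0 ± 6.86 CPM (SD, n = 3, edgeR adjusted p = 0.092), and Fabp7, with 63.3 ± 52.9 and 186 ± 44.2 CPM (SD, n = 3, edgeR adjusted p = 0.095). Of 25 pan and non-myelinating markers, 17 were tested; adjusted over the list alone, Itgb8 was higher and Col28a1 and Cdh2 lower (camera adjusted p = 1). Of 18 myelination genes, 11 were tested and none passed, also adjusted over the list alone (camera adjusted p = 0.098). Pmp22 had 1002 ± 229 and 969 ± 374 CPM and Mpdz 75.2 ± 41.2 and 42.9 ± 3.20 CPM (SD, n = 3). Of 16 repair Schwann cell genes, 13 were tested; Artn and Hmga2 were higher when adjusted over the list alone (camera adjusted p = 0.38, fry adjusted p = 0.0065). Bdnf, a neurotrophin gene of that list, had 617 ± 165 and 522 ± 90.8 CPM, and Jun had 164 ± 65.4 and 178 ± 47.9 CPM (SD, n = 3, edgeR adjusted p = 0.61 and 0.84).

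**Figure D4:**
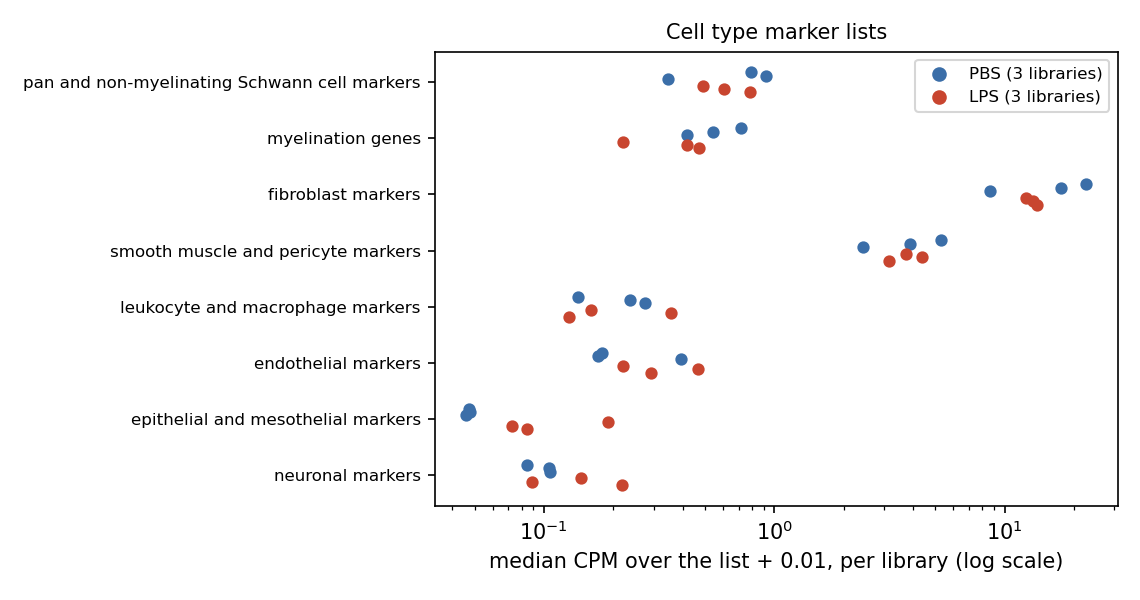
Points are the median CPM + 0.01 over all members of each cell type marker list in 1 library, on a log axis, with PBS in blue and LPS in red (n = 3 each). The median of fibroblast markers lies between 8.63 and 22.7 CPM, and that of pan and non-myelinating Schwann cell markers between 0.337 and 0.909 CPM.

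Genes of the proteins gated against in the sort were low. Ptprc, which encodes CD45, had 1.27 ± 0.332 CPM in PBS and 2.90 ± 0.484 in LPS (SD, n = 3, edgeR adjusted p = 0.093), and Pecam1, which encodes CD31, had 0.688 ± 0.249 and 0.406 ± 0.0930 CPM (SD, n = 3, edgeR adjusted p = 0.29). Epcam had 6 to 12 reads per library and was not tested. Of 23 leukocyte and macrophage markers, 12 were tested and none was called, but without PBS library 3 there were 9 higher and 1 lower (camera adjusted p = 0.045). That fit, also used for the lists below, called 4303 of all 15942 tested genes higher and 4885 lower. S100a8, Csf1r and Ptprc were higher when adjusted over the list alone. That list shifted upward (camera adjusted p = 0.022; adjusted p = 0.70 with an estimated correlation), but not without PBS libraries 1 and 2 (median log2 fold change 0.53 in place of 0.85, adjusted p = 0.25), without LPS library 2 (adjusted p = 0.068) or by fry (adjusted p = 0.20). S100a8, a gene of myeloid cells, had 562 and 666 reads in PBS libraries 1 and 2 and 1914 in PBS library 3, against 1862 to 3495 in LPS. Cd68 had 9.48 ± 4.44 and 15.9 ± 1.77 CPM (SD, n = 3, edgeR adjusted p = 0.16). Of 20 fibroblast markers, 16 were tested and none was called, but without PBS library 3 there were 5 higher and 6 lower. Npnt, Col1a1 and Col3a1 were lower when adjusted over the list alone (camera adjusted p = 0.74). Col1a1 had 91983, 64431 and 11603 reads in PBS and 7010 to 10525 in LPS (edgeR adjusted p = 0.092), and Dcn, which encodes decorin, had 647 ± 323 and 910 ± 82.7 CPM (SD, n = 3, edgeR adjusted p = 0.38). Without that library there were also 2 higher and 6 lower smooth muscle and pericyte markers, 2 and 1 endothelial markers and 2 and 1 neuronal markers. Of 19 smooth muscle and pericyte markers, 16 were tested and none passed, also adjusted over the list alone (camera adjusted p = 0.58). Acta2 had 2934 ± 382 and 2836 ± 698 CPM and Pdgfrb 475 ± 346 and 119 ± 13.8 CPM (SD, n = 3). None of 8 tested endothelial markers of 16 passed, also adjusted over the list alone (camera adjusted p = 0.52), with Flt1 at 1.58 ± 0.462 and 3.24 ± 0.566 CPM and Kdr at 1.77 ± 1.11 and 1.11 ± 0.275 CPM (SD, n = 3). None of 4 tested epithelial and mesothelial markers of 18 passed, too few for camera, with Krt19 at 3.52 ± 1.27 and 3.23 ± 0.583 CPM and Msln at 1.12 ± 0.606 and 0.674 ± 0.369 CPM (SD, n = 3). Of 14 neuronal markers, 5 were tested; Stmn2 was higher when adjusted over the list alone (camera adjusted p = 0.89). Uchl1 had 13.6 ± 7.77 and 18.7 ± 2.11 CPM and Map2 14.0 ± 5.50 and 8.05 ± 1.33 CPM (SD, n = 3).

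No gene of the matrix, growth and metabolic lists was called over all genes with all libraries, but without PBS library 3 many were. Calls were frequent in that fit, with 4303 of all 15942 tested genes higher and 4885 lower. In that fit 1 collagen and matrix gene was higher and 16 lower, 7 and 10 of the proteases, 6 and 8 of the neurotrophic factors, 7 and 9 of the TGF-beta and BMP targets and 2 and 7 of the Notch and Hippo targets. Likewise, 4 cell cycle genes were higher and 12 lower, 4 and 9 of the cholesterol genes and 5 and 6 of the metabolism and hypoxia genes. All 26 collagen and extracellular matrix genes were matched and 24 tested; none passed, also adjusted over the list alone, with Spp1 at 10512 ± 7183 and 19694 ± 2743 CPM and Thbs1 at 9273 ± 4909 and 3999 ± 148 CPM (SD, n = 3). As a list they shifted downward (camera adjusted p = 0.035; adjusted p = 0.79 with an estimated correlation). Without PBS libraries 1 and 2 the median log2 fold change of that list went from -0.76 to 0.08 and camera gave the other direction (adjusted p = 0.77; 0.0023 to 0.79 over all settings). The list was also not called without PBS library 1, LPS library 1 or LPS library 3, with length and GC offsets (adjusted p = 0.61) or by fry (adjusted p = 0.35). Without PBS libraries 1 and 2 the log2 fold change was -0.04 for Thbs1, -0.02 for Col1a1, 0.14 for Pdgfrb, -0.14 for Cdh2, -0.07 for Sema3e and -0.07 for Irak1, with no call among them. Of 24 proteases and matrix remodelling genes, 19 were tested; Plau and Has1 were higher and Adamts1, Mmp2 and Plat lower when adjusted over the list alone (camera adjusted p = 0.99). Timp2 had 2448 ± 539 and 1624 ± 429 CPM and Lox 1954 ± 779 and 1453 ± 181 CPM (SD, n = 3, edgeR adjusted p = 0.26 and 0.45). Of 23 neurotrophic and axon guidance factors, 22 were tested; Artn was higher and Efnb2 lower when adjusted over the list alone (camera adjusted p = 0.79). Sema3e had 222 ± 111 and 91.2 ± 5.17 CPM (SD, n = 3, edgeR adjusted p = 0.094). All 20 TGF-beta and BMP targets were tested; Tgif1 was higher and Ccn1 and Id4 lower when adjusted over the list alone (camera adjusted p = 0.70), with Id3 at 2224 ± 1257 and 5016 ± 719 CPM and Ccn2 at 1809 ± 691 and 1331 ± 169 CPM (SD, n = 3). Of 17 Notch and Hippo targets, 13 were tested; Ajuba was lower when adjusted over the list alone (camera adjusted p = 0.24). Axl had 1104 ± 494 and 616 ± 30.3 CPM and Ankrd1 384 ± 81.7 and 508 ± 37.9 CPM (SD, n = 3). All 25 cell cycle genes were tested and none passed, also adjusted over the list alone (camera adjusted p = 0.38). Rrm1 had 75.7 ± 30.7 and 42.5 ± 4.66 CPM and Cdk1 56.4 ± 22.5 and 57.2 ± 19.0 CPM (SD, n = 3). Of 21 cholesterol biosynthesis genes, 20 were tested; 4 were lower when adjusted over the list alone, among them Lss, Sqle and Dhcr7 (camera adjusted p = 0.42), with Msmo1 at 148 ± 64.0 and 225 ± 5.76 CPM and Sc5d at 141 ± 35.0 and 131 ± 29.1 CPM (SD, n = 3). Of 19 metabolism and hypoxia genes, 18 were tested; Cebpb, Cebpd, Hk2 and Pfkfb3 were higher and Pfkp, Slc2a1 and Ldha lower when adjusted over the list alone (camera adjusted p = 0.79). The transcription factor genes Cebpd and Cebpb had 752 ± 286 and 732 ± 216 CPM in PBS and 2792 ± 241 and 2583 ± 418 CPM in LPS (SD, n = 3, edgeR adjusted p = 0.074 and 0.073).

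Of the 27 lists tested, 9 shifted upward and 1 downward by camera, and 2, the chemokines and the cytokines, were called with an estimated correlation. Against PBS library 3 as the only control, none was called with an estimated correlation (smallest adjusted p = 0.065).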

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

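The settings without PBS libraries 1 and 2 together, with length and GC offsets and with library weights were chosen after seeing the data. The 84 higher and 4 lower genes moved most with the setting: 1516 and 2154 by DESeq2, 1075 and 1962 without the low-count filter, 128 and 27 with length and GC offsets, 5461 and 6139 by limma-voom with library weights, 50 and 1 without PBS libraries 1 and 2, where PBS library 3 is the only control, and 30 and 0 at an adjusted p under 0.01. Leaving out each library in turn gave 24 to 4303 higher and 0 to 4885 lower genes, the highest of each without PBS library 3, and the shifted lists ranged from 6 to 10. Lower genes numbered 2 with upper-quartile factors, 2 at a minimum count of 50 and 0 against 1.5-fold. With an estimated correlation 2 lists were called in place of 10. Upper-quartile factors moved the median log2 fold change of all genes from -0.07 to 0.12. The cause of these differences was not tested, apart from the stricter thresholds. Whether the replicate numbers pair the libraries is not known. The deviations of same-numbered libraries from their group means correlated at 0.17, -0.08 and 0.27. This cannot decide it with 3 libraries per group and PBS library 3 apart from the other PBS libraries. With the replicate block 2144 genes were higher and 2109 lower, with 10 lists shifted, and not every library correlated best with its own number. RLE factors and unweighted limma-voom gave 91 and 94 higher and 3 and 3 lower genes, and all 84 genes kept a positive fold change wherever tested. Of 37 called genes named by the rule, none changed sign in any setting and 17 kept their call with each library left out in turn. Called genes had no overlap between the groups, which all but fixed their sign, so the kept signs add no separate support. Sign changes fell on genes that were not called. Without PBS libraries 1 and 2 the log2 fold changes were 0.44 for Lox, -0.17 for Dcn, 0.024 for Acta2, 0.14 for Pdgfrb, 0.61 for Kdr, 0.43 for Krt19, 0.55 for Msln, -0.28 for Uchl1, 0.0037 for Map2, 0.063 for Rrm1, -0.53 for Cdk1, 0.37 for Ccn2, 0.18 for Axl, -0.20 for Cd14 and 5.91 for Ngfr, which had 0 reads in the only PBS library left, so that its fitted value is no measured fold. With upper-quartile factors they were 0.11 for Pmp22, 0.14 for Acta2, 0.084 for Krt19 and 0.056 for Sc5d, and with RLE factors 0.0041 for Acta2. A minimum count of 50 gave 0.012 for Pmp22 and 0.022 for Acta2, no filter -0.021 for Itgav and -0.027 for Cdk1, library weights -0.22 for Jun and -1.54 for Sox10 (adjusted p = 0.022), and length and GC offsets 0.075 for Xbp1. With each library left out in turn the ranges were -0.20 to 0.30 for Itgav, -0.41 to 0.16 for Pmp22, -0.19 to 0.36 for Jun, -0.26 to 0.11 for Acta2, -0.36 to 0.17 for Krt19, -0.29 to 0.37 for Cdk1, -0.31 to 0.10 for Sc5d and -0.30 to 1.13 for Sox10. The differences in total count, genes detected, mitochondrial share, ribosomal protein share and share of the 100 most abundant genes kept their sign with each library left out. Depth limits genes with few reads, such as Sox10 and Ngfr, whose levels lie near 1 CPM or below.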

Other observations

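The tests of fibroblast share, of Schwann cell markers and of overlapping genes were chosen only after the result was seen. Of the 84 genes higher after LPS, 41 belong to no list fixed in advance. The genes named in this paragraph were chosen after their values were seen. Fas, the death receptor gene, went from 51.9 ± 32.2 to 354 ± 7.53 CPM (SD, n = 3, edgeR adjusted p = 0.025), with 32.4, 34.4 and 89.1 CPM in PBS libraries 1 to 3. The metal-binding metallothionein gene Mt2, with 73.5% of its exonic bases overlapped, had 61.7 ± 51.7 and 612 ± 202 CPM (SD, n = 3, edgeR adjusted p = 0.049), with 27.3, 36.6 and 121 CPM in PBS libraries 1 to 3. Pim1, a serine/threonine kinase gene, rose by 3.06 on the log2 scale, Il13ra2, an interleukin 13 receptor gene, by 2.84, and Bdkrb1, which encodes the bradykinin B1 receptor, by 2.52 (edgeR adjusted p = 0.0050, 0.028 and 0.013). Arg2, a mitochondrial arginase gene, rose by 2.59 (edgeR adjusted p = 0.013), and Gdf15, a TGF-beta family cytokine gene, by 1.75 (edgeR adjusted p = 0.040). Gm16685, antisense to Il7, had 0, 6 and 9 reads in PBS and 295, 590 and 1009 in LPS (edgeR adjusted p = 0.0040).

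PBS libraries 1 and 2 stood apart from PBS library 3. Against a difference in depth, the lowest correlation of PBS library 3 with an LPS library exceeded its mean correlation with PBS libraries 1 and 2 by 0.0389 after all libraries were thinned to the smallest total, as it did unthinned (0.0388). Against another share of fibroblasts as the only cause, 36.4% of 11 abundant fibroblast markers were over 1.5-fold lower in PBS libraries 1 and 2 and 54.5% over 1.5-fold higher. Another share beside other differences is not excluded. Between these libraries 6264 genes differed over 2-fold, which could move markers either way. A bias with transcript length may be part of the cause, since the difference between these libraries followed exon length across genes (Spearman correlation 0.378). After correction for length and GC content the gap was still 0.0213. This argues against it as the whole cause only as far as the correction removed the bias. The correction used annotated exon length, not the length of the transcripts expressed, and may have left part of it. What else sets these libraries apart stays open, and apart from the fibroblast share no biological explanation was tested.

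The list of pan and non-myelinating Schwann cell markers had a low median of 0.660 CPM, although 11 of its 25 members had a mean of at least 1 CPM. Against reads lost to overlapping genes as the cause for the list, the median overlapped share of the markers' exonic bases was 0%. Other genes overlap most of the exonic bases of 4 markers, S100b and Gfap among them, and lost reads may lower those. Cells other than Schwann cells, such as fibroblasts or pericytes, which the sort gated against only through tdTomato, could contribute. The median of fibroblast markers was 21.0 times and that of smooth muscle and pericyte markers 5.60 times the Schwann cell median, with Acta2 at 2934 ± 382 CPM and Col1a1 at 1072 ± 731 CPM in PBS (SD, n = 3). Such cells cannot be told apart from a change of Schwann cells over 8 days of culture, because cultured cells of several types express matrix and contractile genes and no uncultured cells were compared here.

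Ccl2, a monocyte chemokine gene, was listed at 0 in every library, while its neighbour Ccl7 reached 2431 ± 600 CPM in LPS (SD, n = 3). Reads in overlapping genes may have been left uncounted: coding genes with all exons inside other genes were at 0 in every library 58.8 percentage points more often than coding genes without overlap. Ccl2 (chromosome 11, 82035571 to 82037453) lies inside Gm17268, chosen after its values were seen, which itself had 3, 2 and 0 reads in PBS and 56, 90 and 138 in LPS. No biological explanation was tested.

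With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave 84 higher genes and the highest other split 0, so that 1 of 10 splits gave as many. The same held for the 4 lower genes, with 0 in the highest other split and 1 of 10 splits giving as many. These counts of 0 are from edgeR, and the other splits had 24 to 4863 genes at an unadjusted p under 0.05. For the lists, 5 of 10 splits gave at least the 10 of the real split, and the highest other gave 11. Neither the gene counts nor the list counts of these splits measure chance. Every other split mixes PBS and LPS libraries in both of its groups. The LPS difference then widens the spread within groups, which makes gene calls unlikely, and can still shift the lists. The smallest adjusted p of a list was 2.1e-28 in the real split and went down to 4.0e-12 in the other splits.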
